A study of Homo sapiens with 4 samples.

How the data were processed

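RNA from HEK 293T cells treated for 24 h with DMSO or 20 µM embelin was measured on 4 arrays of the Agilent human 4x44K design, in 1 colour (Cy3), with 2 arrays per group. Per the labels' protocols, total RNA was reverse transcribed and amplified by T7 polymerase into labelled cRNA. Per the file headers, the scanner software was Agilent Feature Extraction 9.5.1.1, which gave for each spot an intensity after spatial and multiplicative detrending, with surrogate values for dim spots and no subtraction of the local background. These deposited intensities were not normalized between arrays. The authors also deposited a table of log2 values. Set against the scanner values, differences between its columns correlated at 0.9992 or above with a slope of 1.0. It holds the log2 processed signal, scaled to the 75th percentile and centred per probe on the mean of the 2 DMSO arrays. Its column medians were 0.0037 and -0.0037 for the DMSO arrays and -0.0025 and 0.0782 for the embelin arrays. It served as an alternative source of values.

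From the scanner files, the log2 processed intensity minus each array's 75th percentile was taken. Control spots (1639 of 45015) were left out, as were gene spots marked as non-uniform or population outliers (82 to 116 per array), and saturated spots (5 to 19 per array) were kept. The 10 spots of each of 264 repeated probes were averaged. A probe was tested where it was well above background on both arrays of at least 1 group, which kept 25131 of 41000 probes, with 15799 below the filter and 70 lost to outlier spots. A probe not well above background on either array of a group has only a bound there. Such a change is given as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Where the probe's own signal was the higher on both dim arrays, this equals the fitted fold. It is then given as fitted, not as a minimum. No probe's level was set against another's. Signal over background differed between arrays: the spread of negative control spots was 20.9 for DMSO replicate 1 and between 6.3 and 8.5 on the others.

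Probes were named through the unversioned RefSeq accession in a table of the assembly GRCh38.p14 (26222 probes), its current symbols (1646) or its older symbols (466), and 12666 kept the name in the files. Coordinates are those of the files, on GRCh37, and no annotation of that build was used here, so exon and UTR positions are not given. For 337 of the 13478 genes tested the probe's coordinate lay on another chromosome than the gene. Where a gene had several tested probes, the brightest stood for it.

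Embelin was compared with DMSO by limma (version 3.58.1, R version 4.3.3), with lmFit and eBayes on the log2 values, 2 residual degrees of freedom and 6.4 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors are the moderated ones. Of 34 gene lists fixed before the data were examined, 33 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists. Camera sets a list's genes against all other genes tested, so its direction is relative to them and not to 0. The median of each list was set against 10000 random lists matched on brightness. The test with an estimated correlation and fry were alternatives. Figures were drawn with matplotlib.

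The fit was tested on simulated data of 25131 probes and 2 arrays per group, in which 200 probes were changed. Probe means were the real ones, but spreads were drawn from limma's fitted prior variance, with normal and independent errors. Such data meet the fit's assumptions. They do not check effects of brightness on spread, of DMSO replicate 1 or of correlated genes. The fit called 0% of probes changed by 1 on the log2 scale, 5% of those changed by 2, 72.5% of those changed by 3 and 95% of those changed by 4 or by 5, and 3 unchanged probes. Of 2 lists shifted by 1 and by -0.5 in 13478 simulated independent genes, both were called and 0 of the others.

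Genes were named by a rule fixed before the data were examined. It took up to 12 genes per direction with the largest change among those past the threshold with separate groups and signal well above background in the higher group, where 1 gene passed. It also took KAT2B, KAT2A, XIAP, ALOX5 and PTGES, up to 4 members with the smallest p of each called list in its direction, and up to 2 of each other list. The 12 genes with the smallest p in each direction were added after the values were seen. Some genes that the rule took are not reported here.

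Alternatives fixed beforehand were normexp background correction with an offset of 50, median scaling, quantile normalization, the deposited log2 table, no filter on dim probes, a filter on all 4 arrays, an intensity trend in the prior variance, outlier spots kept, the replicate number as a block, each array left out in turn, an unmoderated t statistic, a minimum change of 1.2-fold inside the test, the list test with an estimated correlation, fry, and the mean of all probes of a gene. With an array left out, its group has 1 sample, which is assumed to vary like the other group. The labels tie no replicate number to a shared culture or day, and 2 pairs cannot show pairing, so the reported fit has no block.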

Results

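Transcript levels were measured in HEK 293T cells, a human embryonic kidney line that carries adenovirus E1A and the SV40 large T antigen, after 24 h with solvent or with embelin. Embelin is a plant benzoquinone described as an inhibitor of XIAP and, in the study's title, of the lysine acetyltransferase PCAF (KAT2B). Cells received DMSO or 20 µM embelin in DMSO, and 2 arrays were hybridised per group. All 4 arrays lay on 1 slide scanned at 1 time, so slide and scan could not differ between the groups. The labels do not say whether the 2 arrays of a group came from separate cultures, and the p-values therefore measure only the spread between these arrays, which may be technical. Each array held 41000 gene probes. The 75th percentile of the processed signal was 613.6 for DMSO replicate 1, 373.8 for DMSO replicate 2, 252.9 for embelin replicate 1 and 271.2 for embelin replicate 2, and between 60.1% and 72.5% of gene spots were well above background. DMSO replicate 1 stood apart: its correlation across probes was 0.954 with DMSO replicate 2, 0.936 with embelin replicate 1 and 0.915 with embelin replicate 2. DMSO replicate 2 reached 0.967 and 0.961 with the embelin arrays, which correlated at 0.96 with each other. By this measure the embelin arrays were no closer to each other than to DMSO replicate 2. The number of arrays limits the precision of every value below.

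The comparison of embelin with DMSO addressed which transcripts change when cells are exposed to this inhibitor. With embelin, 1 gene was far higher, genes of the ATF4 amino acid and stress response rose together, and genes for histones, cholesterol synthesis, proteasome subunits, heat shock proteins and the respiratory chain fell as groups. These group calls come from the list test with a preset correlation between genes of 0.01. None of them passed with an estimated correlation (smallest adjusted p = 0.595), a test with 2 residual degrees of freedom, or with fry (smallest adjusted p = 0.329). For heat shock and respiratory genes the estimated correlations, 0.003 and 0.005, were below the preset one. A larger correlation therefore did not cost those calls. KLHDC7B, a gene for a kelch-domain protein, rose with embelin on both of its probes. Its brighter probe, on chromosome 22 from 50988455 to 50988514 (GRCh37), went from a log2 level of -3.23 ± 0.35 to 2.41 ± 0.87 (SD, n = 2 arrays per group), a log2 difference of 5.64 ± 0.51 (SE) or 49.8-fold (95% confidence interval of the log2 difference, 4.47 to 6.80), with a limma adjusted p of 0.0347. The other probe, from 50989288 to 50989347, was not well above background on either DMSO array and was at least 59.5-fold higher with embelin (adjusted p = 0.004). It entered the test through the embelin arrays alone. Its limma p uses dim DMSO values (-6.09 and -5.88), whose spread may not be a measured one. The KLHDC7B probes were the only ones past the threshold among 25131 tested in the reported setting, 2 higher and 0 lower, and both changed by at least 2-fold. At an unadjusted p under 0.05 there were 2322 probes, 939 higher and 1383 lower, where 1257 were expected with no effect. The unmoderated t statistic called 0 probes, with 1440 at an unadjusted p under 0.05. The brighter KLHDC7B probe missed the threshold with quantile normalization (5.62, adjusted p = 0.0512), where the other probe kept its call, and neither probe passed without the filter on dim probes (adjusted p = 0.381 for the brighter one, 0 probes by limma with 2292 at an unadjusted p under 0.05). The brighter probe's adjusted p ran from 8.09e-12 to 0.787 over the alternatives fixed beforehand. Without DMSO replicate 1 the count was 10, without DMSO replicate 2 it was 140, without embelin replicate 1 it was 114 and without embelin replicate 2 it was 84. Each such fit has 1 array in a group and gave more calls than the fit of all arrays. These counts are therefore no measure of how firm a call is. The brighter KLHDC7B probe's difference was 3.13 with normexp and ran from 5.02 to 6.25 in these 4 runs. Of 108 named genes, KAT2B aside, 49 had a log2 difference that moved by over 1.5 times in at least 1 of these runs.

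GDF15, a stress-induced cytokine of the TGF-beta superfamily, came next in order of p. Its probe on chromosome 19, from 18499890 to 18499949, had log2 levels of -1.06 and -0.04 with DMSO and of 3.96 and 3.94 with embelin. The difference of 4.50 ± 0.46, or 22.6-fold, missed the threshold over all probes at an adjusted p of 0.0657. The difference was 3.99 without DMSO replicate 1, 5.01 without DMSO replicate 2, 4.49 without embelin replicate 1 and 4.51 without embelin replicate 2. Its adjusted p ran from 1.05e-15 to 0.787 over the alternatives fixed beforehand.

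**Figure D1:**
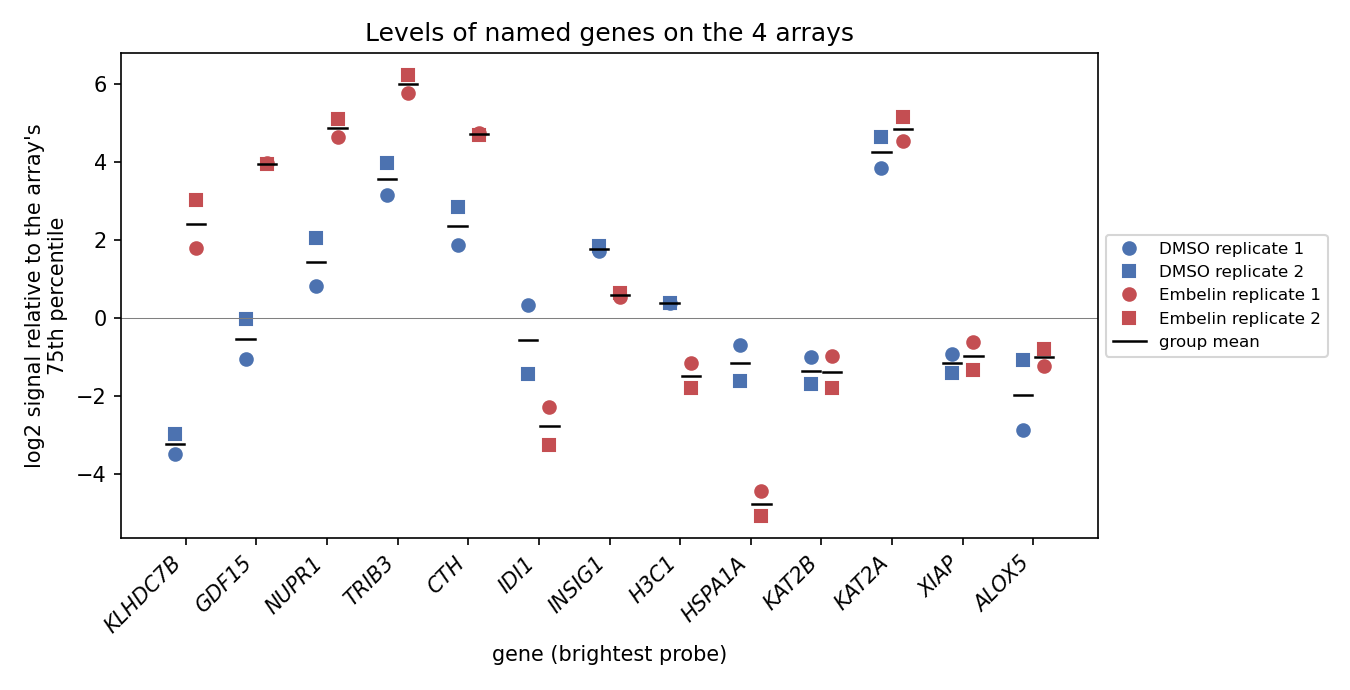
Log2 signal relative to each array's 75th percentile (vertical axis) for 13 named genes (horizontal axis, brightest probe of each), with 1 point per array (blue for DMSO, red for embelin, circles for replicate 1, squares for replicate 2) and a bar at each group's mean of 2 arrays. Both embelin points of KLHDC7B (1.80 and 3.02) lie above both DMSO points (-3.48 and -2.98), and the 2 groups of KAT2B overlap.

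KAT2B itself, the acetyltransferase named as the target, did not differ detectably at the transcript level. Its brighter probe, on chromosome 3 from 20195519 to 20195578, had log2 levels of -1.01 and -1.70 with DMSO and -0.97 and -1.80 with embelin. The difference was -0.03 ± 0.47 (adjusted p = 0.991), with a 95% confidence interval from -1.11 to 1.06, so that changes of about 2-fold either way were not excluded. The second KAT2B probe gave 0.65 ± 0.40 (adjusted p = 0.609). The sign of the brighter probe's difference was positive with median scaling (0.09), with quantile normalization (0.06), without DMSO replicate 1 (0.32) and without embelin replicate 2 (0.39), and no alternative brought it past the threshold. KAT2A (GCN5), the paralogue of KAT2B, differed by 0.59 ± 0.46 (95% confidence interval -0.47 to 1.65). Among other proteins reported to bind embelin, XIAP, an inhibitor of caspases, differed by 0.18 ± 0.45, and ALOX5, the 5-lipoxygenase, by 0.96 ± 0.60. Neither passed the test. Without DMSO replicate 1 the values were 0.19 for KAT2A and 0.06 for ALOX5, without DMSO replicate 2 they were 0.99 and 1.87, and the sign for XIAP turned without DMSO replicate 2 (-0.07) and without embelin replicate 1 (-0.18). PTGES was not well above background on any array and was not tested. With 3 measured members, the list of reported embelin targets was too short for the list test. In the list of PCAF/GCN5 acetyltransferases and SAGA/ATAC subunits, 13 of 26 genes were higher and 13 lower (median 0.00, camera adjusted p = 0.775). TAF5L (-1.54 ± 0.40) and TADA2B (-1.46 ± 0.45) had its smallest p-values, at adjusted p of 0.379 and 0.423.

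Genes of the amino acid and stress response driven by the transcription factor ATF4 rose together with embelin. Of 39 measured genes, 35 were higher, and in 26 of these both embelin arrays lay above both DMSO arrays. Chance alone would part the groups one way or the other in 33.3% of genes, and 42.4% of all tested probes did so. The median log2 difference of the list was 1.17 (camera adjusted p = 1.23e-13). This call was not kept with an estimated correlation between genes (adjusted p = 0.595), a test with 2 residual degrees of freedom in which no list passed. No member passed the threshold over all probes, and 19 passed when adjusted over the list alone, all of them higher. After GDF15, the members with the smallest p were NUPR1, a stress-induced chromatin protein (3.43 ± 0.51), TRIB3, a pseudokinase that restrains ATF4 (2.44 ± 0.45, with a second probe at 0.45 ± 0.41), and CTH, which makes cysteine from cystathionine (2.36 ± 0.46). CHAC1, which breaks down glutathione, differed by 2.58, the transcription factors CEBPB and ATF3 by 1.84 and 2.02, and the amino acid transporter SLC7A5 by 1.62, with a second SLC7A5 probe at 0.36. These 4 and the ones that follow were named after their values were seen. DDIT3 (0.76 ± 0.53) and ASNS (0.58 ± 0.52) did not pass even over the list alone. The brighter ATF4 probe was saturated on 1 embelin array, so its difference of 0.71 ± 0.45 can be compressed, and the other ATF4 probe gave 0.05 ± 0.41. The differences of PHGDH (0.12), AARS1 (-0.09) and ATF5 (0.05) were close to 0. The camera call was kept without each array in turn, with medians from 0.86 to 1.21. With normexp background correction alone it was kept narrowly (camera adjusted p = 0.0386). The list median there was 0.64, where the median of all probes was 0.507. When quantile normalization followed, the list median was 0.63 (camera adjusted p = 6.03e-12) and that of all probes 0.004.

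**Figure D2:**
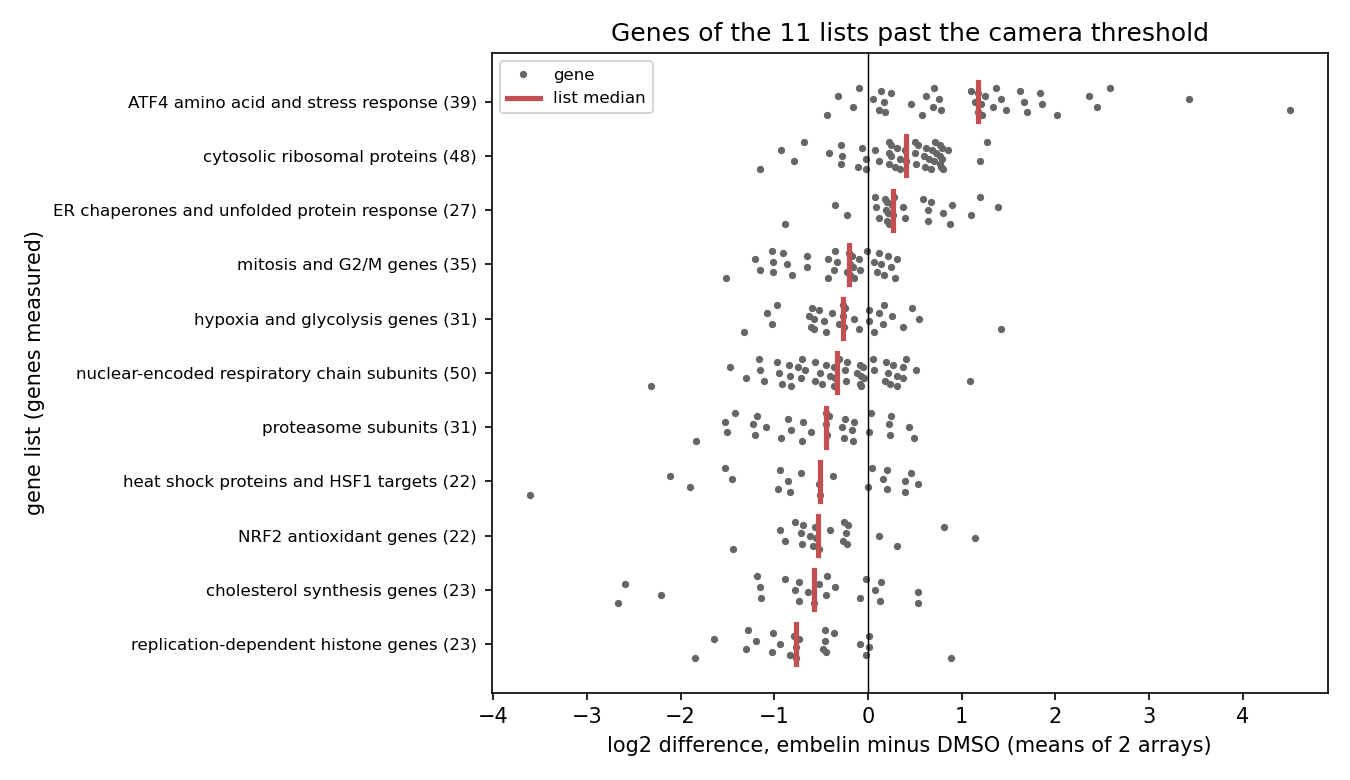
Log2 difference between embelin and DMSO (horizontal axis, means of 2 arrays each) for every measured gene of the 11 lists past the camera threshold (vertical axis, number of genes in parentheses), with a red bar at each list's median. The ATF4 list has 35 of 39 genes above 0 and the histone list 20 of 23 below 0. The ribosomal list's test direction turned with quantile normalization. With the normexp correction the ribosomal median turned (-0.37), and the ER list's test turned while its median stayed at 0.07. That correction also left the ER, histone and NRF2 lists uncalled.

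Replication-dependent histone genes, which supply nucleosomes during DNA synthesis, fell. Of 23 measured genes, 20 were lower, 15 of them with separate groups, and the median was -0.77 (adjusted p = 7.5e-07). With an estimated correlation this call was lost (adjusted p = 0.595). H3C1 differed by -1.85 ± 0.42, H2BC3 by -1.30 ± 0.43 and H1-3 by -1.19 ± 0.40. H4C8 was not well above background with embelin and was 3.11-fold lower as fitted, which is no minimum. None passed over all probes or over the list alone, where the smallest adjusted p was 0.0503. Histone genes of one class are close in sequence, and probes may not separate them. The call was kept without each array in turn (medians -0.85 to -0.60). It was not kept with normexp background correction (median 0.05, adjusted p = 0.332), which also turned the signs of H2BC3 and H4C8, and the median was -0.35 when quantile normalization followed.

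Genes of cholesterol synthesis fell as a group: 18 of 23 were lower, with a median of -0.58 (adjusted p = 2.94e-05, and adjusted p = 0.685 with an estimated correlation). No member passed over all probes and 2 passed when adjusted over the list alone, both lower. NSDHL, which is among them and encodes an enzyme of the late steps, was not well above background on either embelin array and was at least 1.96-fold lower, a sign that turned with normexp. IDI1, which isomerises isopentenyl diphosphate, differed by -2.21 ± 0.63, and INSIG1, a sterol sensor of the ER, by -1.18 ± 0.39, and neither passed over the list alone. The fatty acid synthesis and SREBP1 list did not pass (median -0.13, adjusted p = 0.362), with FABP5 at -1.36 ± 0.41 and SREBF1, which encodes SREBP1, at 1.39 ± 0.46. The size of the cholesterol shift rested partly on DMSO replicate 1: without that array the median was -0.19 (adjusted p = 0.00358).

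Proteasome subunits fell, with 24 of 31 genes lower and a median of -0.45 (adjusted p = 2.94e-05, and adjusted p = 0.685 with an estimated correlation). PSMA2 (-1.53 ± 0.44), PSMC3 (-1.42 ± 0.42), PSMB3 (-1.23 ± 0.43) and PSMA7 (-1.83 ± 0.69, and -0.67 without embelin replicate 2) led the list. Heat shock proteins and other HSF1 targets had a median of -0.51, with 13 of 22 lower (adjusted p = 0.00109, and adjusted p = 0.595 with an estimated correlation). HSPA1A, the inducible HSP70, had 3 probes. Its brightest, well above background on 1 of 2 embelin arrays, stood at -3.61 ± 0.48. Of the others, not well above background with embelin, 1 was at least 9.64-fold lower and 1 had a fitted log2 difference of -2.7 ± 0.57. The brightest probe passed over the list alone, not over all probes (adjusted p = 0.139). Its sign turned with normexp (0.18), and it may also read the near-identical HSPA1B. The co-chaperones DNAJA1 (-1.45 ± 0.42) and STIP1 (-1.90 ± 0.59) and the chaperone HSP90AB1 (-1.52 ± 0.50) came next, with the sign of STIP1 turned by normexp. The deposited coordinates place the STIP1 and HSP90AB1 probes on chromosomes other than those of the genes, as for a processed copy. Nuclear-encoded respiratory chain subunits had a median of -0.33, with 36 of 50 lower (adjusted p = 0.00109, and adjusted p = 0.595 with an estimated correlation). Among them were ATP5MC1 (-1.47 ± 0.46, its probe likewise placed on another chromosome), SDHC (-1.30 ± 0.47, turned by normexp), ATP5F1C (-2.31 ± 0.89, and -0.84 without embelin replicate 2) and ATP5F1B (-1.16 ± 0.48). All 3 camera calls were kept without each array, but their medians moved. Without DMSO replicate 1 they were -0.17 for the proteasome, -0.24 for heat shock and -0.15 for the respiratory chain. Without DMSO replicate 2 they were -0.71, -0.90 and -0.35. The heat shock median was also -0.25 without embelin replicate 2 and -0.95 with the mean of each gene's probes. With normexp the proteasome median was -0.90 and the respiratory median -0.83. The medians of DMSO replicate 1 minus DMSO replicate 2 were 0.38, 0.45 and 0.28 in these lists.

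**Figure D3:**
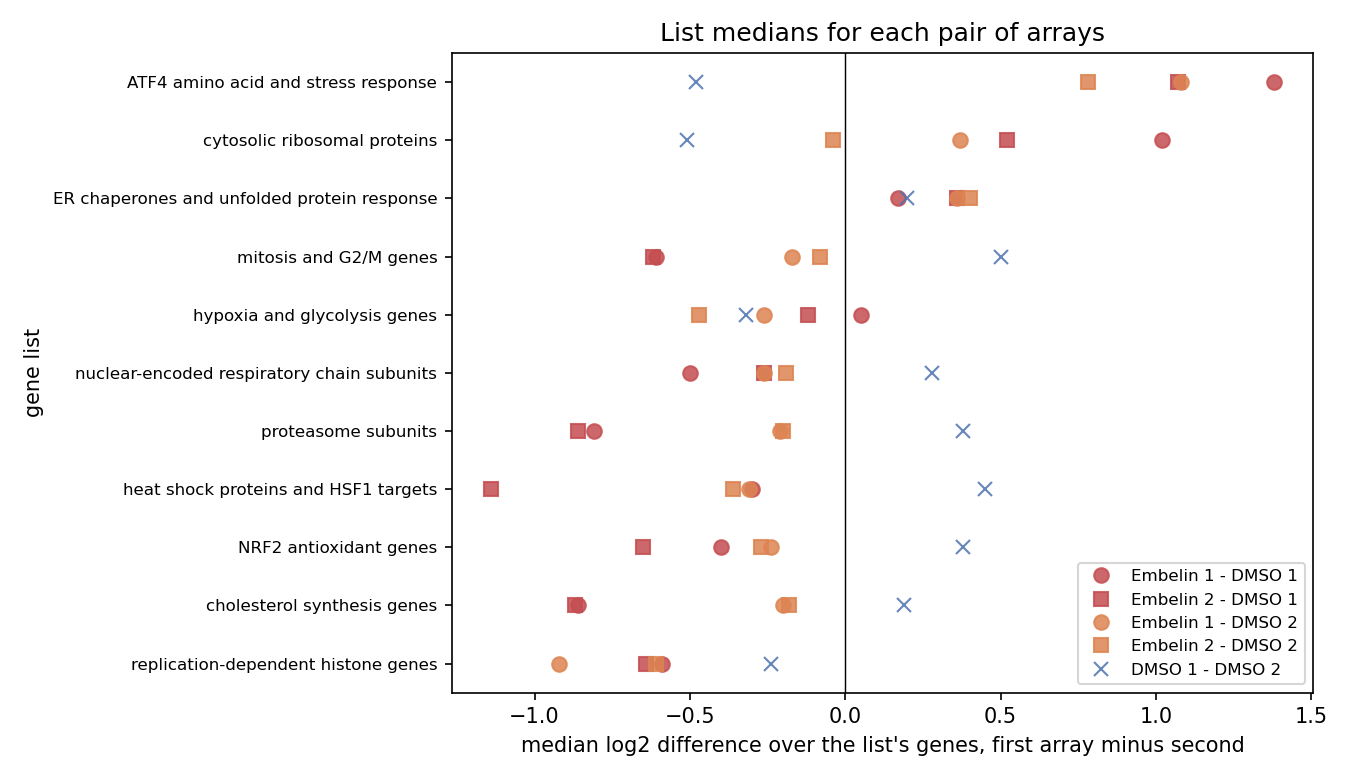
Median log2 difference over each list's genes (horizontal axis) for the 4 pairs of an embelin and a DMSO array and for the 2 DMSO arrays (first array minus second), by gene list (vertical axis). For proteasome genes the pairs with DMSO replicate 1 gave -0.81 and -0.86, those with DMSO replicate 2 gave -0.21 and -0.20, and DMSO replicate 1 exceeded DMSO replicate 2 by 0.38.

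In 5 further lists the call was lost without at least 1 of the arrays. Mitosis and G2/M genes were lower (26 of 35, median -0.20, adjusted p = 0.00247, and adjusted p = 0.685 with an estimated correlation), with KIF20A (-1.20 ± 0.41), AURKA (-1.15 ± 0.46), AURKB (-1.02 ± 0.44, turned by normexp) and CCNB1 (-1.01 ± 0.44) first. Without DMSO replicate 1 the median was 0.01 (adjusted p = 0.333), and without DMSO replicate 2 it was -0.46. NRF2 antioxidant genes had a median of -0.53 with 18 of 22 lower (adjusted p = 0.00902, and adjusted p = 0.685 with an estimated correlation). Among its lower genes, the peroxiredoxin PRDX1 (-1.44 ± 0.41), PGD (-0.94 ± 0.49), SQSTM1 (-0.70 ± 0.41) and GCLM (-0.88 ± 0.54) had the smallest p. Without DMSO replicate 1, PGD stood at -0.33 and GCLM at -0.14. The list's call was lost without DMSO replicate 1 (-0.30), without embelin replicate 2 (-0.34) and with normexp (-0.27, adjusted p = 0.214). Hypoxia and glycolysis genes had a median of -0.27 with 20 of 31 lower (adjusted p = 0.0448, and adjusted p = 0.685 with an estimated correlation). The lower genes with the smallest p were the glycolytic enzymes TPI1 (-1.08 ± 0.46, with a second probe at -0.41), PGAM1 (-1.32 ± 0.58), PGK1 (-0.97 ± 0.44) and ENO1 (-1.02 ± 0.52). Without DMSO replicate 1 these stood at -0.62, -0.46, -0.6 and -0.4. The list lost the call without DMSO replicate 2 (median 0.00) and without embelin replicate 2, where the median hardly moved (-0.28). The TPI1 probe is placed on another chromosome than its gene, and without such probes the list kept its median of -0.27 at an adjusted p of 0.073.

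Endoplasmic reticulum chaperones and genes of the unfolded protein response were higher in 24 of 27 cases (median 0.27, adjusted p = 0.0145, and adjusted p = 0.685 with an estimated correlation), a direction that the list test turned with normexp (median 0.07, adjusted p = 0.197). XBP1 (1.39 ± 0.45) and ATF6 (1.1 ± 0.52, second probe 0.27), transcription factors of that response, and SEL1L (1.2 ± 0.41) and SYVN1 (0.90 ± 0.39, second probe 0.03), which act in ER-associated degradation, had the smallest p. The call was lost without DMSO replicate 2 (0.30, adjusted p = 0.278), without embelin replicate 1 (0.45, adjusted p = 0.108), with quantile normalization (0.30, adjusted p = 0.0939) and with cyclic loess (0.30, adjusted p = 0.105), none of which made the median smaller, and with normexp followed by quantile normalization (0.20, adjusted p = 0.0714), which did, and without DMSO replicate 1 the median was 0.41. Cytosolic ribosomal protein genes had a median of 0.41 with 36 of 48 higher (adjusted p = 0.0174, and adjusted p = 0.821 with an estimated correlation), a direction that turned with quantile normalization (median 0.00, adjusted p = 0.364), with cyclic loess (adjusted p = 0.955) and with normexp (-0.37, adjusted p = 5.75e-06). RPS6 (1.27 ± 0.50), RPL19 (1.2 ± 0.55), RPLP1 (0.86 ± 0.43) and RPS15 (0.80 ± 0.41, second probe 0.22) led the list. Bright probes in general were higher with embelin: of 5 equal groups of probes by brightness, the brightest had a median difference of 0.19 and the dimmest one of -0.20. Among random lists of like brightness the percentile of the median was 21.9 for the ribosomal list and 80.6 for the ER list. Both medians lay inside the central range of those lists, 0.32 to 0.61 and -0.05 to 0.4. Neither rise was therefore larger than lists of like brightness gave. The ribosomal call was lost without DMSO replicate 1 (0.23, adjusted p = 0.435), without embelin replicate 1 (0.21, adjusted p = 0.714), with the mean of each gene's probes (0.14, adjusted p = 0.423) and without probes placed on another chromosome (0.30, adjusted p = 0.392), and the median was 0.77 without DMSO replicate 2 and 0.62 without embelin replicate 2.

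The other 22 lists did not pass, with medians from -0.25 to 0.59 and adjusted p from 0.205 to 0.917. Targets of p53, which HEK 293T cells hold bound to large T antigen, had a median of 0.00. GDF15, which also belongs to the ATF4 list, passed over that list alone. BBC3 stood at 1.61 ± 0.50, with its other probes at -0.67 and -0.02, and the cell cycle inhibitor CDKN1A, named after its value was seen, at 0.40, with a second probe at -0.02. Genes of E2F and DNA replication had a median of -0.13, with RFC2 at -1.18 and CCNE2, well above background on 1 embelin array, at -1.48, and DNA repair genes a median of 0.26, with XRCC5 at -1.73 and BLM at 1.02. The E2F list passed, lower, with quantile normalization (-0.24, adjusted p = 0.0292), cyclic loess (-0.25, adjusted p = 0.0245) and normexp (-0.42, adjusted p = 0.000447), and the MYC list named next passed, lower, with normexp (-0.63, adjusted p = 0.000221). The median was -0.25 for PPAR targets and lipid oxidation (CPT2 -0.98, ACADVL 1.05), -0.02 for the IAP family and caspase pathway (CASP6 -1.02, CYCS -1.29, other CYCS probes -1.77 and 0.00) and -0.02 for MYC targets and ribosome biogenesis (GNL3 1.01, by a probe placed on another chromosome, MRTO4 -1.04). Lysosome and autophagy genes had a median of -0.13, and ATP6V0D2, a vacuolar proton pump subunit not well above background on 1 DMSO array, passed over that list alone at 2.91 ± 0.49, with GABARAPL2 at -0.83. Histone deacetylases and sirtuins had a median of 0.36 (HDAC6 0.89 with a second probe at -0.53, SIRT5 0.89 with other probes at 1.18 and 0.02) and other lysine acetyltransferases one of -0.07 (ESCO2 -1.54, KAT7 -0.70).

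NF-kB targets had a median of -0.17 (TRAF1 1.58, IER3 -1.26), which became -0.63 and passed without DMSO replicate 1 (adjusted p = 1.86e-06). Immediate early genes had a median of 0.00, with KLF2 at 1.62, a second KLF2 probe at -0.27, and DUSP5 passing over the list alone but not well above background with embelin and at least 2.19-fold lower. This list was called lower without DMSO replicate 1 (-0.33, adjusted p = 0.000302) and higher without DMSO replicate 2 (0.69, adjusted p = 0.0184). The median of DMSO replicate 1 minus DMSO replicate 2 was -1.13 in the NF-kB list and -0.82 in the immediate early list. Interferon-stimulated genes had a median of 0.01 but a mean of -0.15 (IFIT1 -1.19, BST2 -1.37), TGF-beta targets one of -0.17 (ID3 -1.62, BMP4 at least 1.75-fold lower and not well above background with embelin), metallothioneins and zinc response genes one of -0.12 (SLC30A1 -1.23, MT1X -0.77, list called with normexp and quantile normalization at -0.30, adjusted p = 0.0456) and aryl hydrocarbon receptor targets one of -0.03 (AHRR 0.88, CYP1A2 -1.03). Markers of other cell types gave medians of 0.59 for 6 epithelial and keratinocyte genes (KRT8 1.02, by a probe placed on another chromosome, CLDN7 1.68), 0.05 for 9 kidney tubule genes (CUBN -1.44, SLC12A3 -1.84, mean of the list -0.26), -0.21 for 10 neuronal genes (TUBB3 -1.23 with a second probe at -0.01, INA 0.88), 0.32 for 5 leukocyte genes (CD3E 1.35, CD14 -0.69) and 0.21 for 5 fibroblast genes (ACTA2 0.61, COL1A1 0.47). Of these, CLDN7 and CD3E were well above background on 1 DMSO array, and CUBN and SLC12A3 on 1 embelin array. Without embelin replicate 1, CUBN stood at -0.01 and SLC12A3 at -0.16, and without DMSO replicate 1 CLDN7 stood at -0.06 and CD3E at 0.50. Leaving out 1 array gave 3 further calls. The epithelial list passed, higher, without DMSO replicate 2 (1.13), and the kidney list, lower, without embelin replicate 2 (-0.16). The list of other lysine acetyltransferases passed, lower, without DMSO replicate 2 (-0.32). The PCAF/GCN5 list, at -0.15, did not pass in that run. With normexp the kidney list was called higher (1.53, adjusted p = 0.00604).

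Since a single gene passed, the genes with the smallest p in each direction were also read, a choice made after the values were seen. None beyond KLHDC7B passed over all probes. On the higher side, GDAP1L1 stood at 3.26 ± 0.40 (adjusted p = 0.114), FUT1, a fucosyltransferase, at 3.59 ± 0.48 and FBLL1, a fibrillarin-like gene, at 2.89 ± 0.42, followed by the calcium-binding S100P (3.04), MFAP4 (3.08) and BEST1 (3.80). GDAP1L1, MFAP4 and BEST1 were well above background on 1 DMSO array, while C2orf80 and P2RX1 were not well above background with DMSO and were at least 6.39-fold and at least 2.82-fold higher. On the lower side, the pacemaker channel HCN2 stood at -3.20 ± 0.40 (adjusted p = 0.114), the homeobox gene PHOX2A at -2.07 ± 0.40 and PARD6G at -2.70 ± 0.51, with a second PARD6G probe at 0.00. HOXA3 (-2.40) and the dopamine receptor DRD4 (-2.50) each had a second probe of the opposite sign, at 1.26 and 0.91. NOD1, S1PR1, TMEM135, TENM3-AS1 and PNMA6A were not well above background with embelin. S1PR1, TENM3-AS1 and PNMA6A were at least 3.96-fold, 2.83-fold and 2.08-fold lower. As fitted, NOD1 was 5.32-fold and TMEM135 6.86-fold lower, which are no minima, and a second TMEM135 probe gave -1.1.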

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

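The rule for the control probes was set after the data were examined and looked for higher probes only. Of 93 control probes on the arrays, which the comparison does not use, 9 were above background on both embelin arrays, and 2 of these were higher on both embelin arrays than on both DMSO arrays, an order that chance gives to 16.7% of probes. On the log2 scale relative to each array's 75th percentile, AT_ssH_AB_3 had 5.11 and 5.64 with DMSO and 6.03 and 5.72 with embelin. The group means differed by 0.50, but its unscaled signals had the reverse order. They were 16502.01 and 14308.21 with embelin and 21197.67 and 18703.14 with DMSO. On the same relative scale AT_ssH_PC_3 had 1.53 and 1.43 with DMSO and 1.73 and 2.42 with embelin, a difference of 0.59. Its unscaled signals overlapped, at 1774.73 and 1005.27 with DMSO and 837.44 and 1448.77 with embelin. Of the same 9, AT_ssH_RR_5 was lower with embelin, at unscaled signals of 261.49 and 115.8 against 1531.37 and 1561.57 with DMSO. AT_ssH_AB_5 was also lower, at 122.98 and 139.53 against 957.22 and 350.82. The arrays' 75th percentiles were 252.9 and 271.2 with embelin and 613.6 and 373.8 with DMSO. What these falls reflect was not tested, nor whether they bear on the gene comparisons.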

How the results depend on the processing

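Of the alternatives below, normexp followed by quantile normalization, cyclic loess and leaving out probes placed on another chromosome were chosen after seeing the data. A slide block was not run, since all arrays lay on 1 slide. Precision was limited by 2 arrays per group and by signal over background, and 43 probes in DMSO and 491 in embelin were measured only as bounds there.

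The count of 2 probes past the threshold, all of at least 2-fold, became 3 with median scaling, 2 with the deposited log2 table, with outlier spots kept and with the minimum change inside the test, 9 with the filter on all 4 arrays, 4 with an intensity trend, 1 with quantile normalization or cyclic loess, and 0 with no filter, with the unmoderated t statistic or with normexp and quantile normalization, where limma's or the plain statistic gave 2292, 1440 and 1994 probes at an unadjusted p under 0.05. Without moderation the test has 2 residual degrees of freedom by construction. With no filter, 40898 probes were tested and the prior degrees of freedom went from 6.4 to 5.1, and the cause of that loss, as of the other changes, was not tested. With quantile normalization or cyclic loess the 1 probe was of KLHDC7B. Left out in turn, single arrays gave 10 to 140 probes, 4 of which passed in all 4 runs (both of KLHDC7B, GDF15 and C2orf80). The correlation of DMSO replicate differences with embelin replicate differences was 0.17 across probes, and with the replicate number as a block the counts were 2 probes and 11 lists, with no call changed.

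With normexp 11314 probes passed (9807 higher, 1507 lower), 10102 of them by at least 2-fold, and the median of all probes moved to 0.507 (0.112 with median scaling, -0.004 as reported). Its offset of 50 is fixed while the arrays' 75th percentiles ran from 252.9 to 613.6, so dim probes rise on dim arrays by construction, and after quantile normalization 0 probes passed and the median of all probes was 0.004. Signs that turned under normexp alone were those of AURKB (0.98), BMP4 (1.70), CASP6 (0.17), CCNE2 (1.59), CD14 (1.38), CPT2 (0.10), CUBN (1.73), DUSP5 (1.67), ESCO2 (0.42), H2BC3 (0.25), H4C8 (1.48), HSPA1A (0.18), KAT2A (-0.23), KAT7 (0.82), NOD1 (1.02), NSDHL (1.5), PNMA6A (1.82), RFC2 (0.37), RPLP1 (-0.16), S1PR1 (1.34), SDHC (0.82), SLC12A3 (1.54), SLC30A1 (0.36), STIP1 (0.89), TENM3-AS1 (1.73) and TMEM135 (0.89). List tests turned for DNA repair (-0.14), ER chaperones (median 0.07), NF-kB (0.57), PPAR (0.17), TGF-beta (0.31), ribosomal proteins (-0.37), deacetylases (0.00), immediate early (-0.10), interferon (0.66), kidney (1.53), neuronal (0.15) and other acetyltransferases (0.43).

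KAT2B turned positive with normexp (0.46), median scaling (0.09), quantile normalization (0.06), normexp with quantile normalization (0.04), cyclic loess (0.03) and the mean of its probes (0.31), and ranged from -0.44 to 0.39 with arrays left out. Its adjusted p ran from 0.346 to 1, so none of these signs is distinguishable from 0.

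The 11 called lists became 0 with an estimated correlation and 0 with fry, whose smallest adjusted p were 0.595 and 0.329, and 9 to 12 in all other settings, where 8 to 11 were the same lists. The ATF4, cholesterol, proteasome, heat shock and respiratory lists kept their calls in each of the 4 runs without an array and the 12 other refits. Of these refits, the intensity trend does not enter the list test, and the deposited log2 table holds nearly the same values. Neither of those 2 is a separate check. The histone list lost its call under normexp alone. Ribosomal proteins turned with quantile normalization (0.00), cyclic loess (0.11, a positive median with a negative test) and normexp with quantile normalization (-0.12). Uncalled lists turned as follows: aryl hydrocarbon receptor (-0.03) and neuronal (-0.21) with the mean of probes, immediate early (0.12) with median scaling and (0.00) with the block, kidney (0.08) with the filter on all 4 arrays, and aryl hydrocarbon receptor (-0.04), immediate early (-0.06) and kidney (0.03) with normexp and quantile normalization. With arrays left out, values that turned ranged from -0.07 to 0.12 for MYC targets, -0.63 to 0.41 for NF-kB, -0.15 to 0.21 for PCAF and SAGA, -0.29 to 0.27 for the aryl hydrocarbon receptor, -0.24 to 1.13 for epithelial, -0.32 to 0.64 for fibroblast, -0.33 to 0.69 for immediate early, -0.16 to 0.33 for kidney, -0.15 to 0.70 for leukocyte, -0.35 to 0.01 for lysosome, -0.70 to 0.50 for neuronal and -0.32 to 0.14 for other acetyltransferase genes, -0.18 to 0.54 for XIAP and -0.06 to 3.42 for CLDN7. Medians of called lists also moved by over 1.5 times for respiratory genes with median scaling (-0.21), quantile normalization (-0.51) and cyclic loess (-0.53), for mitosis genes with these (-0.09, -0.37 and -0.38), normexp (-0.62) and the mean of probes (-0.33), for hypoxia genes with median scaling (-0.15), normexp (-0.53) and the mean of probes (-0.47), and for NRF2 genes with normexp and quantile normalization (-0.28), all with the call kept. Medians and list tests differed in sign in some of these. The list test's direction is relative to all other genes, while the median's sign is relative to 0.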

Other observations

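Of the tests below, those on base composition and on the neighbours of KLHDC7B were written before their results were seen, and those on brightness, DMSO replicate 1, the other KLHDC7B probe and DNA replication only after. Each pattern was found and tested on the same 4 arrays.

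The ATF4 list was higher with embelin. A trend with brightness would place its median inside the range of random lists of like brightness, and so would base composition for random lists of like GC content, but the median lay at percentile 100 of both. DMSO replicate 1, which stood apart, is not the whole cause, since the median without it was 0.96 and the call was kept. A response of these genes to embelin stays open, as a hypothesis.

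Of the 8 lists lower with embelin, 6 stayed lower past the threshold without DMSO replicate 1, which argues against that array as their whole cause, although the medians shrank to -0.17 for the proteasome, -0.19 for cholesterol synthesis, -0.24 for heat shock and -0.15 for the respiratory chain, so part of their size may come from it. For the mitosis list the median without that array was 0.01 and each other array could be left out with the call kept, in line with DMSO replicate 1 as its source. Base composition is argued against for all 8, since 0 of the medians lay inside the central range of random lists of like GC content. Fewer cells in DNA replication could lower histone genes. The E2F and DNA replication list had a median of -0.13, with 19 genes higher and 22 lower. This median lay at percentile 0.05 of random lists of like brightness. It lay at percentile 3.16 of those of like GC content, inside their central range. The list passed with quantile normalization (-0.24), cyclic loess (-0.25) and normexp (-0.42) and not as reported, so that the question stays undecided.

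KLHDC7B was higher with embelin on both probes. A faulty spot or cross-hybridization of 1 probe is argued against by the other probe, which was at least 59.5-fold higher. Its fitted difference of 6.70 is no measured size, since it was not well above background with DMSO. A change of the chromosome region would raise its neighbours, but the 10 tested genes within 250 kb had a median of 0.29, and 0 of them differed by 1 or more. A change in the transcript's level with embelin is a hypothesis.

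Embelin replicate 1 minus embelin replicate 2 had a median of 0.24 for genes whose probes have at most 35% GC and of -0.51 for those above 55%. Between the groups, the medians of those bins were 0.13 and -0.02. Probes not well above background in 1 group alone numbered 491 with embelin and 43 with DMSO.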
